A study of Mus musculus with 8 samples.

How the data were processed

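Bone marrow-derived macrophages (BMMs) grown with macrophage colony-stimulating factor (M-CSF) were profiled by RNA-seq in 8 mouse libraries, 4 with the genotype label Ogfrl1 knockout (KO) and 4 labelled wild type. Per the labels' protocols, non-adherent marrow cells were grown with M-CSF at 25 ng/mL for 4 days, RNA was isolated by phase separation with Ribozol, and libraries were made with a KAPA mRNA Hyper Prep kit. Groups were taken from the genotype label. Replicates were numbered in accession order within each group, and nothing in the labels pairs a KO library with a wild-type library. The sample titles carry a different number for each library. The labels do not say whether each number is a separate animal, so p-values measure the spread between these libraries, part of which can be technical.

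The deposited workbook held mapping statistics and a table of 11541 genes. Its count columns are raw read counts per gene made by the authors with STAR alignment to UCSC mm10 and featureCounts, per the file headers and the submitters' processing notes. Tool versions, the annotation release, the strand setting of featureCounts and the filter that removed other genes are not given in the sources used here. In the mapping statistics most coding reads lay on the strand opposite to the annotation, 12.7 to 14.0% of reads against 0.09 to 0.11% in sense, so the libraries kept strand, but whether counting used it is open. The 11541 genes held 99.943 to 99.961% of the reads on genes in each library. Every gene had at least 0.502 CPM (counts scaled to library size) in at least 4 libraries. Mitochondrially encoded genes were absent from the rows, and 532 rows carried predicted or clone-type names. The deposited log2 FPKM columns, per the file headers, are the authors' fragment counts scaled to gene length and library size. They were set beside log2 values per kilobase from library-scaled counts computed here and differed from them by 1 offset per library between -0.02 and 0.05, so the tests used the counts and the log2 values served only this check. The deposited fold change, log2 fold change, p-value and false discovery rate columns are the authors' own comparison, made with a tool that is not stated in the file. The percentages of ribosomal RNA, mitochondrial and uniquely mapped reads per library are also the authors', from bowtie2, bamutils and STAR per the file headers.

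Total counts in the table ranged from 39601341 to 61556269 per library. No pair of libraries differed by as little as sampling noise: the chi-square per degree of freedom over genes ranged from 7.25 to 346. No deposited column of per-sample values was left unused.

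KO was compared with wild type by edgeR 4.0.16 (quasi-likelihood test, TMM factors, two-sided) in R 4.3.3. The default expression filter by group removed no gene, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors and 95% confidence intervals of log2 fold changes were taken from the F statistic and the moderated degrees of freedom. Ogfrl1 was also tested by an exact two-sided permutation test of log2 CPM over 70 assignments, whose smallest possible p is 0.0286. The same exact test served 20 library measures. Values per group are mean ± SD of TMM-scaled CPM, with n = 4 in each group.

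Chosen before the data were examined were the test, the comparison, the other settings listed next, 36 gene lists of pathways, cell types and quality markers, and the rule for named genes. The rule took Ogfrl1, then genes past the threshold. As none passed, it took the 20 genes with the smallest p among those with a mean log2 CPM of at least 1, no overlap between groups and no predicted or clone-type name, leaving out Xist and Y-linked genes, and up to 4 members of each list with the smallest p. Lists with at least 3 tested members (30 lists) were tested as sets with camera of limma 3.58.1 on log2 CPM (prior count 2), with the preset correlation of 0.01. The same lists were tested with a correlation estimated per list and with fry. Mouse Reactome sets of fgsea 1.28.0 with 10 to 300 tested members (794 sets) were tested by camera with both correlations, after 99.7% of genes had been matched to Entrez identifiers by symbol. Genes within 10 Mb of Ogfrl1 were set against all others by Fisher's exact test. Coordinates are those of the deposited table (mm10).

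Other settings fixed at that time were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, at least 1 CPM in 4 libraries, limma-voom without and with quality weights, other thresholds, the mean log2 CPM of Y-linked genes as a covariate, 1 surrogate variable (sva 3.50.0), and each library left out in turn. Chosen after the data were seen were the fits without wild-type replicates 1 and 2, also without KO replicate 2, covariates for the ribosomal RNA percentage and the stromal list, and a correction for GC content. For the last, the log2 CPM deviation of each library from the gene mean was smoothed on transcript GC content (loess, span 0.3) and used as an offset in edgeR. GC content came from GENCODE transcripts of the same genome build and was found for 11471 genes (99.4%). All 35 splits of the 8 libraries into 4 and 4 were refitted.

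The procedure was tested on simulated counts for the 11541 genes, with the means, library sizes and dispersions of these libraries and 200 changed genes in each of 5 runs. For KO against wild type, edgeR recovered 38.4% of genes changed 1.5-fold, 76% of those changed 2-fold and 98.4% of those changed 4-fold. It called 0.04% of unchanged genes. Each gene was drawn independently, without the differences between libraries that many genes share in the real counts. These rates therefore may not hold for the real libraries. Tables were read with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9. Intron and exon usage of Ogfrl1 and the reads themselves were not analysed here.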

Results

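Messenger RNA was sequenced from BMMs, primary macrophages expanded from marrow cells with the growth factor M-CSF, to compare libraries labelled Ogfrl1 knockout (KO) with libraries labelled wild type. The design gave 1 comparison, 4 libraries against 4, all after 4 days in culture. Total counts of the 11541 genes ranged from 47779990 to 53567289 in the KO-labelled libraries and from 39601341 to 61556269 in wild type. Lyz2, the macrophage lysozyme, took 1.198 to 1.609% of all counts in each of the 8 libraries.

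The targeted gene was examined first. Ogfrl1 (opioid growth factor receptor-like 1) lies on the minus strand of chromosome 1 (23366424 to 23383175, mm10) with 7 listed exons. Its transcript was counted in all libraries, with 7309 to 12356 reads in each. The mean was 163 ± 23.7 CPM (library-scaled read counts) in the KO-labelled libraries and 213 ± 73.8 CPM in wild type (SD, n = 4). KO replicates 1 to 4 had 158.9, 197.3, 149.5 and 145.7 CPM, and wild-type replicates 1 to 4 had 267.3, 284.2, 165.8 and 134.9 CPM, so the groups overlapped and the lowest value belonged to a wild-type library. The log2 fold change of KO over wild type was -0.39 (SE 0.24, 95% CI -0.92 to 0.15), with an edgeR adjusted p of 0.404 and an exact permutation p of 0.314. Without wild-type replicates 1 and 2 it was 0.12. Whole-gene counts therefore neither showed a loss of the transcript nor checked the genotype labels, and they hold no information on which exons were read. Its relative Ogfr, the opioid growth factor receptor, had 52.8 ± 6.80 CPM against 44.7 ± 13.7 CPM in wild type, and Penk, the precursor of the enkephalin peptides that Ogfr binds, had 1.777 ± 0.423 against 1.599 ± 0.212 CPM. Neither passed the edgeR test (adjusted p = 0.462 and 0.602), and both differences changed sign under other settings.

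**Figure D1:**
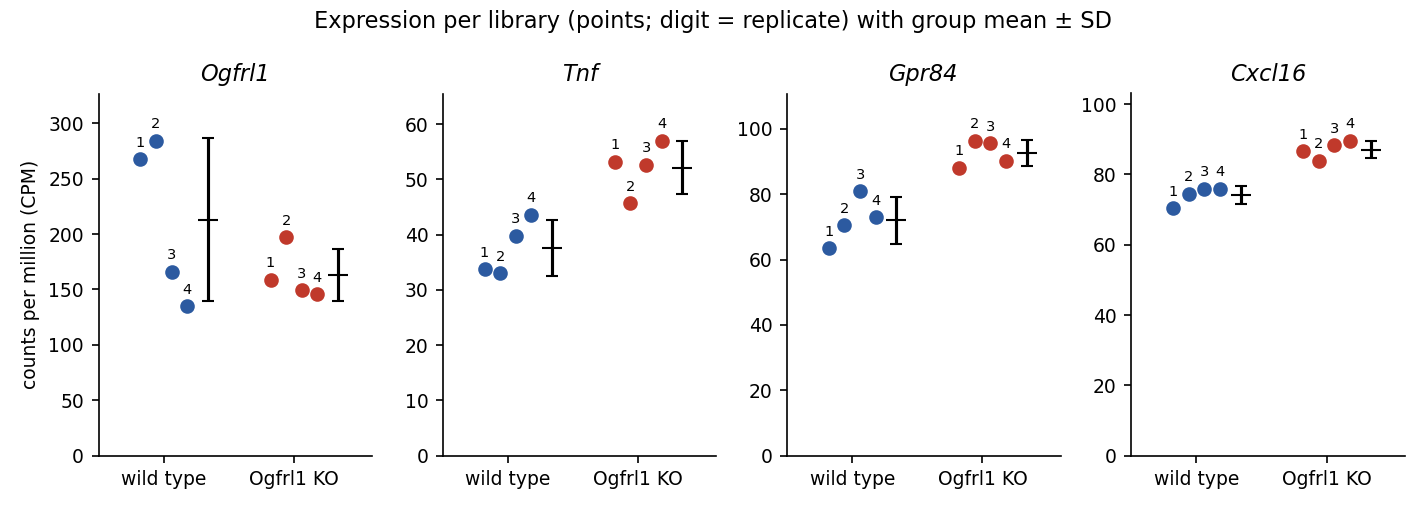
Expression of Ogfrl1, Tnf, Gpr84 and Cxcl16 in CPM (vertical axes from 0), 1 point per library with its replicate digit, blue for wild type and red for the KO label, beside the group mean and SD. Ogfrl1 overlapped between groups, with wild-type replicates 1 and 2 at 267.3 and 284.2 CPM, while for the other genes all 4 KO-labelled libraries lay above all wild-type libraries. Tnf, Gpr84 and Cxcl16 were named by a rule that required no overlap between groups, so their separation was fixed by that choice.

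No gene passed the test between the genotypes. Among 11541 genes, edgeR called 0 at an adjusted p under 0.05, and the lowest adjusted p was 0.404. At an unadjusted p under 0.05 there were 752 genes (6.5%, where chance gives 5%), 232 with higher and 520 with lower values in the KO-labelled libraries. Groups did not overlap in 305 genes (2.6%, where chance gives 2.9%). These chance shares are averages, and genes moved together across libraries. Other splits of the libraries into 4 and 4 gave from 17 to 6813 genes at an unadjusted p under 0.05. The 95% CI of the log2 fold change lay within -1 and 1, a 2-fold change, for 10444 genes (90.5%). It lay within a 1.5-fold change either way for 6954 genes (60.3%). Smaller changes are left open by these intervals. DESeq2 called 1 gene, Cxcl16, at an adjusted p of 0.0456 with 1178 genes at an unadjusted p under 0.05, and limma-voom called 0, with 535. With library quality weights limma-voom called 3065 genes higher and 3097 lower, and the weights ran from 0.185 for wild-type replicate 4 to 3.67 for KO replicate 1. Without wild-type replicate 4, edgeR still called 0 genes, but 5207 had an unadjusted p under 0.05 and 4629 an adjusted p under 0.1. In that fit the log2 fold changes followed transcript GC content across genes (Spearman rho = 0.74).

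Of the 20 named genes with the smallest p, none of which passed, 9 had higher values in the KO-labelled libraries. Tnf (chromosome 17, 35199367 to 35202007), the cytokine tumour necrosis factor, had 52.1 ± 4.73 CPM against 37.6 ± 5.07 CPM in wild type (SD, n = 4), a log2 fold change of 0.47 (SE 0.11). Gpr84 (chromosome 15, 103308235 to 103310438), a receptor for medium-chain fatty acids, had 92.5 ± 4.03 against 72.0 ± 7.16 CPM, a log2 fold change of 0.36 (SE 0.08). The chemokine gene Cxcl16 (chromosome 11, 70454234 to 70459984) had 87.1 ± 2.49 against 74.2 ± 2.63 CPM, a log2 fold change of 0.23 (SE 0.06). The Toll-like receptor gene Tlr2 had 175 ± 8.26 against 149.0 ± 10.3 CPM. The glucose transporter gene Slc2a1 had 66.0 ± 3.89 against 55.1 ± 4.44 CPM, and the Polycomb gene Cbx7 2.93 ± 0.17 against 1.92 ± 0.45 CPM. Micall2, Bcl3, an atypical member of the IκB family, and Dcakd had log2 fold changes of 0.29, 0.30 and 0.30, which became -0.01, -0.11 and -0.01 after a correction for GC content. The other corrected values were 0.38 for Tnf, 0.18 for Gpr84, 0.21 for Cxcl16, 0.23 for Tlr2, 0.10 for Slc2a1 and 0.39 for Cbx7. The edgeR adjusted p before the correction was 0.404 for each of these genes.

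On the other side, Malat1, an abundant nuclear long non-coding RNA, had 1801 ± 171 CPM in the KO-labelled libraries against 2344 ± 255 CPM in wild type (SD, n = 4), a log2 fold change of -0.38 (SE 0.10). Chpt1, a cholinephosphotransferase of phosphatidylcholine synthesis, had 24.1 ± 0.84 against 31.4 ± 4.84 CPM, and the ABC transporter gene Abca9 17.9 ± 1.62 against 22.3 ± 1.64 CPM. Less abundant genes were Psma8, a proteasome subunit best known from testis, with a log2 fold change of -0.56 (SE 0.14), the transcription factor gene Rfx3 with -0.36 (SE 0.11), Bhlhb9 with -0.45 (SE 0.14), the flavin monooxygenase gene Fmo5 with -0.35 (SE 0.11) and the orphan receptor gene Gpr34 with -0.50 (SE 0.16). The zinc finger genes Zfp944 and Zfp945 (-0.68 and -0.41) and the ribosomal protein pseudogene Rps15a-ps6 (-0.76) belong to gene families, and reads shared with relatives were not examined here. After the GC correction the log2 fold changes were nearer 0: -0.19 for Malat1, -0.08 for Chpt1, -0.17 for Abca9, -0.40 for Psma8, -0.12 for Rfx3, -0.42 for Bhlhb9, -0.21 for Fmo5, -0.20 for Gpr34, -0.36 for Zfp944, -0.09 for Zfp945 and -0.64 for Rps15a-ps6. None of these passed the test (edgeR adjusted p = 0.404 for each before the correction).

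Inflammatory genes under control of the transcription factor NF-κB were the list nearest to a difference. Of 19 tested members, 14 had a positive log2 fold change (median 0.10) and 6 had an unadjusted p under 0.05, all with higher values in the KO-labelled libraries, but 0 passed over all genes by edgeR. Adjusted over the list alone, 1 member, Tnf, passed (edgeR p adjusted over the list alone = 0.0446). Il1b, encoding interleukin-1β, had 0.94 ± 0.25 against 0.52 ± 0.08 CPM, the chemokine gene Ccl4 28.2 ± 2.42 against 23.5 ± 1.32 CPM, and Tnfaip3, a negative regulator of NF-κB, 39.7 ± 1.001 against 33.8 ± 2.87 CPM (SD, n = 4). As a set the list missed the threshold in camera of limma (adjusted p = 0.0714, and adjusted p = 0.929 with an estimated correlation) and in fry (adjusted p = 0.125). It passed camera with the preset correlation without KO replicate 1 (adjusted p = 0.0264), KO replicate 3 (0.0156), wild-type replicate 1 (0.000535) or wild-type replicate 2 (0.0175), and after the GC correction (0.000655). It also passed without wild-type replicates 1 and 2 (camera adjusted p = 0.00000254), without these and KO replicate 2 (0.000855) and with the ribosomal RNA covariate (0.000499). It missed the threshold without KO replicate 2 (camera adjusted p = 0.196), KO replicate 4 (0.0835), wild-type replicate 3 (0.188) or wild-type replicate 4 (0.202), and with the stromal covariate (0.0991). With the estimated correlation it passed in none of these 13 settings (adjusted p from 0.205 to 0.990).

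**Figure D2:**
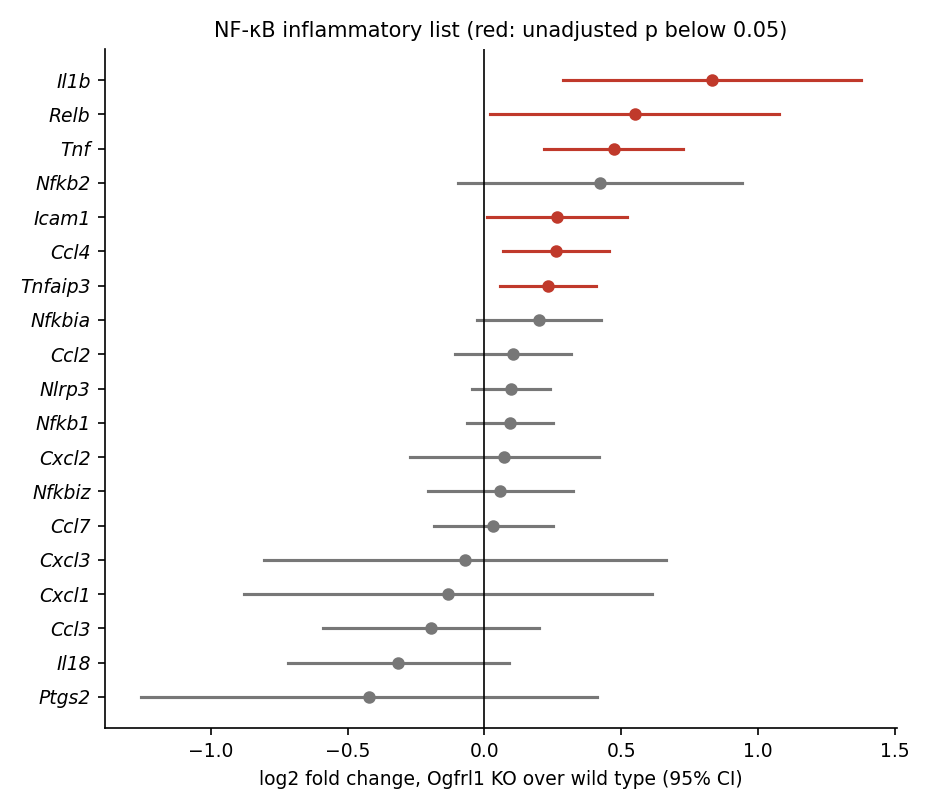
Log2 fold change of Ogfrl1 KO over wild type (horizontal axis) for the 19 tested members of the NF-κB inflammatory list, with 95% confidence intervals from edgeR as lines. Members at an unadjusted p under 0.05 are red. All 6 of them lay above 0, from 0.23 for Tnfaip3 to 0.83 for Il1b. Il1b was counted at a low level, with a mean of 0.94 CPM in the KO-labelled and 0.52 CPM in the wild-type libraries.

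Macrophage and osteoclast programmes did not differ by the same tests. For macrophage identity, 0 of 21 tested members passed over all genes or adjusted over the list alone (median log2 fold change 0.09, camera adjusted p = 0.341). The scavenger receptor gene Marco had 46.1 ± 5.42 against 34.3 ± 7.29 CPM, Cd14, the lipopolysaccharide co-receptor, 89.3 ± 7.17 against 71.0 ± 16.3 CPM, the mannose receptor gene Mrc1 1291 ± 94.8 against 1506 ± 187 CPM, and Spi1, encoding the myeloid factor PU.1, 210 ± 16.9 against 178 ± 18.8 CPM, a difference whose sign turned after the GC correction. Of 18 osteoclast genes 0 passed either way (median 0.17, camera adjusted p = 0.606). Tcirg1, a proton pump subunit needed for bone resorption, had 389 ± 62.2 against 294 ± 77.6 CPM, and Ostm1, the beta subunit of the chloride-proton exchanger ClC-7, 112 ± 3.77 against 130 ± 17.3 CPM. Of 23 genes of Sh3bp2, Syk and Toll-like receptor signalling, 0 passed either way (median 0.01, camera adjusted p = 0.935). Its member with the smallest p was Tlr2, given above, with a log2 fold change of 0.23. It was the only member at an unadjusted p under 0.05. The tyrosine kinase gene Btk, next by p, had 125.9 ± 7.24 against 144.5 ± 15.45 CPM. For the M-CSF response, 0 of 22 passed (median 0.07, adjusted p = 0.374).

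Other immune lists were likewise without a call over all genes, adjusted over the list alone or as sets. Interferon-stimulated genes had a median log2 fold change of 0.02 over 27 members (camera adjusted p = 0.866), with Isg15 at 2.21 ± 0.36 against 1.66 ± 0.31 CPM and the RNA sensor gene Ifih1 at 32.9 ± 2.098 against 40.95 ± 9.19 CPM. Alternative activation had a median of -0.07 over 14 members (adjusted p = 0.763), class II antigen presentation 0.21 over 9 (0.341), chemokine receptors and migration 0.00 over 21 (0.927) and matrix remodelling -0.07 over 24 (0.866). In the last 2 lists the formyl peptide receptor gene Fpr2 had 3.001 ± 0.318 against 2.12 ± 0.38 CPM, and the membrane protease gene Mmp14 19.95 ± 2.35 against 11.9 ± 5.37 CPM. The class II median was -0.89 between wild-type replicates 1 and 2 and the other wild-type libraries. Without wild-type replicates 1 and 2, the class II median of KO over wild type turned to -0.12 (camera adjusted p = 0.0572).

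Metabolic and stress lists also gave 0 called members over all genes, 0 adjusted over the list alone and no set call. Glycolysis and hypoxia had a median log2 fold change of 0.16 over 22 members (camera adjusted p = 0.102, and adjusted p = 0.929 with an estimated correlation), with Gapdh at 1810 ± 110.5 against 1412 ± 363 CPM. The median of this list was -0.36 between wild-type replicates 1 and 2 and the other wild-type libraries. Cell cycle genes had a median of -0.07 over 30 members (adjusted p = 0.341), with topoisomerase gene Top2a at 658.5 ± 42.7 against 781 ± 108 CPM and the centromere protein gene Cenpf at 147 ± 22.5 against 210.0 ± 67.3 CPM. The median was -0.01 for cholesterol synthesis over 24 members, where Cyp51 had 126.5 ± 16.8 against 154.2 ± 24.35 CPM, 0.03 for lipid uptake and efflux over 17, where the lipoprotein lipase gene Lpl had 288 ± 4.02 against 341 ± 46.0 CPM, 0.08 for lysosome over 30 and 0.02 for oxidative phosphorylation over 29, where Cox6c had 55.5 ± 4.09 against 78.0 ± 19.1 CPM. Medians of the unfolded protein response (22 members), NRF2 (20) and heat shock (13) lists were -0.01, 0.00 and -0.11. In the first of these lists Trib3 had 1.34 ± 0.36 against 0.70 ± 0.25 CPM. Its next members by p had lower values in the KO-labelled libraries. Dnajc3 had 272 ± 20.3 against 328 ± 60.3 CPM, Hsp90b1 2177 ± 347 against 2830 ± 679 CPM and Dnajb9 38.9 ± 5.97 against 59.2 ± 26.4 CPM. The haem oxygenase gene Hmox1 had 1299 ± 45.1 against 1112 ± 80.0 CPM. The superoxide dismutase gene Sod1 had 135 ± 13.5 against 172 ± 29.9 CPM and the chaperonin gene Hspd1 385 ± 32.7 against 453 ± 54.9 CPM. The camera adjusted p was 0.341 or higher for each of these last 8 lists. After the GC correction the log2 fold change was -0.07 for Lpl in place of -0.24, 0.09 for Hmox1 in place of 0.22, 0.13 for Tcirg1 in place of 0.40 and 0.29 for Junb in place of 0.61. It was also smaller in size for Mrc1 (-0.05 in place of -0.22), Top2a (-0.07 in place of -0.25) and Ifih1 (-0.11 in place of -0.31). Some other members grew in size, such as Lcn2 (-0.57 in place of -0.37) and Fpr2 (0.62 in place of 0.495). Without wild-type replicates 1 and 2, oxidative phosphorylation (camera adjusted p = 0.0114) and alternative activation (0.000880) passed with lower values in the KO-labelled libraries, as did matrix remodelling (0.0300) without these and KO replicate 2, and none with the estimated correlation. The median and the direction of the camera test differed in sign for matrix remodelling, cholesterol synthesis and the unfolded protein response, and the mean and the test for matrix remodelling, the Sh3bp2 list and NRF2.

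Markers of other marrow cell types gave no call with all 8 libraries and no covariate, but some did under other settings. For neutrophils and their precursors, 0 of 17 members passed over all genes or adjusted over the list alone (median -0.07, camera adjusted p = 0.374), and the 3 members at an unadjusted p under 0.05 all had lower values in the KO-labelled libraries: S100a8 (24.8 ± 3.65 against 32.4 ± 4.15 CPM), S100a9 (52.3 ± 4.68 against 64.3 ± 9.13 CPM) and Lcn2 (14.3 ± 1.69 against 18.5 ± 2.80 CPM). Stromal and osteoblast markers had a median of -0.34 over 7 members (adjusted p = 0.814) with a wide spread between libraries: Col1a2, a collagen of mesenchymal cells, ranged from 3.76 CPM in wild-type replicate 1 to 42.3 CPM in wild-type replicate 4, with group means of 14.96 ± 9.22 and 19.3 ± 16.4 CPM. Medians were 0.03 for monocyte, 0.13 for dendritic cell, 0.02 for megakaryocyte and platelet, 0.16 for endothelial and -0.18 for haematopoietic progenitor markers (adjusted p from 0.341 to 0.866). With the preset correlation of camera, the stromal list passed with lower values in the KO-labelled libraries without wild-type replicate 1 (adjusted p = 0.0124), and the neutrophil list with the ribosomal RNA covariate (0.0221). Without wild-type replicates 1 and 2, the neutrophil (camera adjusted p = 0.0000507), stromal (0.0000484) and progenitor (0.00433) lists passed, and the stromal list (0.0000215) also without these and KO replicate 2. None passed with the estimated correlation. The direction of the stromal list turned without wild-type replicate 4, with a median of 0.37 (camera adjusted p = 0.947). B cell, erythroid, mast cell and eosinophil lists had 1, 1, 2 and 2 tested members and none of these was called, and no T or NK cell marker was among the rows.

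Libraries differed more by a structure that followed genotype only in part, as the libraries it set apart were both wild type. The first principal component of log2 CPM held 70.8% of the variance and set wild-type replicates 1 and 2 (42.9 and 37.1) apart from the other 6 libraries (-24.6 to 7.3). Its mean was -12.9 ± 13.9 in the KO-labelled and 12.9 ± 32.5 in the wild-type libraries. Wild-type replicates 1 and 2 had 1.79 and 1.83% ribosomal RNA reads and 6.07 and 7.03% mitochondrial reads, where the others had 2.71 to 9.10% and 1.49 to 3.17%. Uniquely mapped reads were 76.4 and 75.8% in them and 83.83 to 87% in the others. Across genes, which are not independent replicates, the log2 fold change of KO over wild type followed transcript GC content (Spearman rho = 0.72), and rho was 0.09 without wild-type replicates 1 and 2. Genes at an unadjusted p under 0.05 had a median GC content of 42.9% where lower and 55.4% where higher in the KO-labelled libraries, against 49.3% over all genes. None of 20 library measures passed between genotypes by the exact permutation test (lowest p = 0.0571, Benjamini-Hochberg adjusted 0.571). Its smallest possible p is 0.0286, so a measure that differed alone could not pass after adjustment over 20. The result does not show that the groups were alike. Mitochondrial reads averaged 2.09 ± 0.73% in the KO-labelled and 4.25 ± 2.71% in the wild-type libraries, and uniquely mapped reads 85.4 ± 1.38% and 80.7 ± 5.28%. Without wild-type replicates 1 and 2, edgeR called 0 genes and 115 had an unadjusted p under 0.05.

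**Figure D3:**
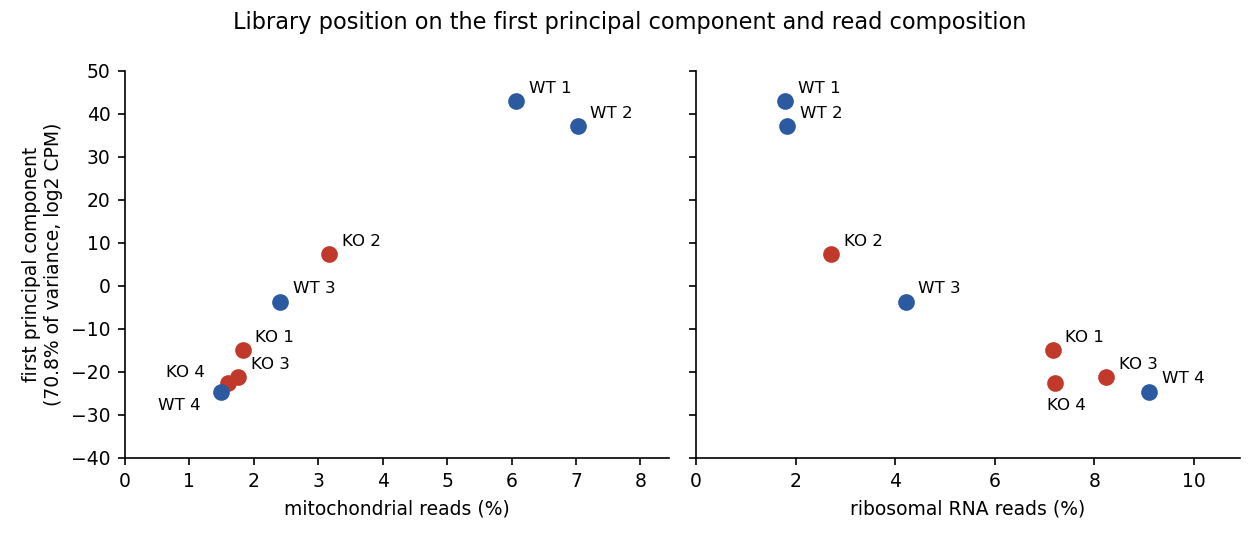
Position of the 8 libraries on the first principal component of log2 CPM (vertical axis) against the percentage of mitochondrial reads (left) and of ribosomal RNA reads (right), 1 point per library, blue for wild type (WT) and red for the KO label. Wild-type replicates 1 and 2 sit apart at 42.9 and 37.1, with the highest mitochondrial and the lowest ribosomal RNA percentages.

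Quality lists gave no call with all 8 libraries and no covariate. Immediate early genes, which respond to handling, had a median log2 fold change of 0.12 over 16 members (camera adjusted p = 0.341), with Junb at 78.6 ± 16.4 against 51.4 ± 21.7 CPM, and cytosolic ribosomal protein genes 0.15 over 30 (0.341). Y-linked genes were read in all 8 libraries with a median of -0.28 over 4 members (0.212). Their mean log2 CPM, used above as a covariate, was 6.37 and 6.02 in wild-type replicates 1 and 2 and 5.74 to 5.94 in the others. That covariate therefore also followed the libraries that stood apart. Xist, the remaining member of the list, was not among the rows. That list passed camera with the preset correlation without wild-type replicate 2 (adjusted p = 0.0452) but not with the estimated correlation (adjusted p = 0.897), and its median was 0.03 after the GC correction. For immediate early genes the median after the correction was -0.05. No mitochondrially encoded gene was among the rows.

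Genes linked to the targeted locus were examined because knockout alleles can carry flanking sequence of another strain. Of 24 tested genes within 10 Mb of Ogfrl1, 0 were called by edgeR, as were 0 of the 11516 others, so the count of calls could not show linkage. All of the 24 except Mcm3, Gsta3 and Paqr8 had a negative log2 fold change, which was not tested. For Eya1, Terf1, Phf3, Smap1 and Tram1, among others, wild-type replicates 1 and 2 had the highest values of all libraries. For Sdhaf4 and Rpl7, among others, they did not. Eya1 had 7.79 and 9.45 CPM in these replicates and at most 5.45 CPM in the other libraries. At an unadjusted p under 0.05 there were 3 (12.5%, against 6.5% elsewhere, Fisher's exact test, two-sided p = 0.203): Eya1, the Toll-like receptor 4 co-receptor gene Ly96 and Tceb1, with log2 fold changes of -0.58, -0.64 and -0.29. Those of Ly96 and Tceb1 turned to 0.01 without wild-type replicates 1 and 2 and after the GC correction, respectively. Camera called 0 of 794 Reactome sets, and 0 with an estimated correlation (lowest adjusted p = 0.996). The authors' deposited table also held 0 genes at a false discovery rate under 0.05 (lowest 0.447) and 968 at a p under 0.05, of which 644 were among the 752 above. Its log2 fold changes and those of edgeR correlated at Pearson r = 0.9999 across genes, and it listed Ogfrl1 at -0.39 with a false discovery rate of 0.447.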

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

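No outlier test was chosen after the results were seen, but some of the genes checked were picked after them. Outliers were sought in 164 groups of 4 libraries (library measures and named genes in each genotype) by the gap of the highest or lowest library to its nearest neighbour relative to the group's range. Chance marks about 1 in 20 such groups, and 6 were found.

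KO replicate 2 stood apart from the other KO-labelled libraries in 4 of these. It had 3.17% mitochondrial reads, against 1.6 to 1.83% in the others. Its score on the second principal component, which held 12.4% of the variance, was -12.8, against 7.74 to 11.6. Penk was at 2.41 CPM in it, against 1.53 to 1.58 CPM, and Ly96 at 11.1 CPM, against 9.29 to 9.37 CPM.

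Bcl3 was at 19.7 CPM in KO replicate 3, against 16.2 to 16.7 CPM in the other KO-labelled libraries. Gpr34 was at 3.91 CPM in wild-type replicate 2, against 2.77 to 2.87 CPM in the other wild-type libraries.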

How the results depend on the processing

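Fits without wild-type replicates 1 and 2 or without these and KO replicate 2, the ribosomal RNA and stromal covariates, the GC correction and the unadjusted threshold near Ogfrl1 were chosen after the data were seen. The cause of a change was not tested unless stated. The count of called genes was 0 in edgeR under the other normalizations, filters, thresholds, covariates and with each library left out (0 to 0, with a lowest adjusted p from 0.0877 to 0.765 over these 8 fits), 1 in DESeq2 and 6162 in limma-voom with quality weights, whose log2 fold changes followed GC content with rho = 0.74. The authors' deposited table held 968 genes at its unadjusted p under 0.05. Near Ogfrl1, 0 genes were called in windows of 5, 10 and 20 Mb, and 0 of 10, 3 of 24 and 10 of 98 had an unadjusted p under 0.05. List members called stayed at 0 in all 16 other settings run for them. Limma-voom with quality weights was not among these settings, and in that fit Ogfrl1, itself a list member, passed (limma adjusted p = 0.0126). As that fit called 6162 of 11541 genes, this says little about Ogfrl1 in particular. How many other list members passed in it was not counted.

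The log2 fold change of Ogfrl1 was -0.55 to -0.22 with each library left out, -0.65 with quality weights (limma adjusted p = 0.0126), 0.04 with the Y-linked covariate, 0.12 without wild-type replicates 1 and 2 and 0.01 without these and KO replicate 2. Camera with the preset correlation called 0 to 2 lists with each library left out, 6 without wild-type replicates 1 and 2, 3 without these and KO replicate 2, 2 with the ribosomal RNA covariate and 1 after the GC correction. With the estimated correlation none of these calls held (adjusted p from 0.205 to 0.990).

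Named genes whose sign turned were, after the GC correction, Micall2 (-0.01), Bcl3 (-0.11), Dcakd (-0.01), Spi1 (-0.07), Ogfr (-0.04) and Tceb1 (0.01). With the Y-linked covariate Ogfr was at -0.06, and without wild-type replicates 1 and 2 Ogfr was at -0.08 and Ly96 at 0.01. Penk ran from -0.03 without KO replicate 2 to 0.22 without KO replicate 3, and was at -0.04 without KO replicate 2 and wild-type replicates 1 and 2. Col1a2 ran from -0.86 without KO replicate 2 to 0.36 without wild-type replicate 4, and was at 0.07 with the stromal covariate. Tnip3 was at -0.01 with quality weights and ran from -0.03 without wild-type replicate 4 to 0.23 without wild-type replicate 1. At these depths edgeR recovered 38.4% of simulated 1.5-fold changes, so smaller differences would mostly go uncalled. The simulation left out differences between libraries that many genes share, so this share is only a guide.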

Other observations

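The tests on GC-corrected values, without wild-type replicates 1 and 2 and with the stromal covariate, and the genes named in this paragraph, were chosen after the results were seen. After the GC correction edgeR called 0 genes (709 at an unadjusted p under 0.05, lowest adjusted p = 0.547). The genes given here were picked by hand from those with the smallest p, and no theme among them was tested. Tnf had a log2 fold change of 0.38 (SE 0.06), Cxcl16 0.21 (SE 0.04), Tnip3, an inhibitor of NF-κB signalling, 0.42 (SE 0.09), the apoptosis inhibitor gene Birc3 0.22 (SE 0.05) and Irg1, which makes itaconate in activated macrophages, 0.42 (SE 0.11). Before the correction Tnip3 was at 0.07 and Birc3 at 0.14. Rasgrp3, a Ras activator, and Enc1 were at -0.48 (SE 0.12) and -0.26 (SE 0.07).

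The higher values of the NF-κB inflammatory list in the KO-labelled libraries may reflect genotype, but this is a hypothesis from 1 list that was the strongest of 30. Against wild-type replicates 1 and 2 as the only source, fry, a rotation test and not an exact one, still gave p = 0.0138 without them (median log2 fold change 0.12). In that fit markers of other cell types also had lower values in the KO-labelled libraries. Medians were -0.90 for the stromal, -0.18 for the neutrophil and -0.26 for the progenitor list (camera with the preset correlation, adjusted p = 0.0000484, 0.0000507 and 0.00433). None of these lists passed with the estimated correlation (camera adjusted p = 0.547, 0.499 and 0.547). Without wild-type replicate 4 alone, the stromal median was instead 0.37. Against a different content of stromal cells, the same test, likewise not exact, gave p = 0.0101 with the stromal covariate, and against GC content p = 0.00139 on corrected values (median 0.15). Of the 35 splits of the libraries into 4 and 4, 1, the genotype split, gave a fry p as small (0.00418, lowest other 0.0554), a count that leaves out the choice among 30 lists. A different content of neutrophils or progenitors was not tested on the list and stays open. Handling differences between the cultures had no test set for the list and stay open too: the immediate early list, which responds to handling, had a median of 0.12, and -0.05 after the GC correction, where the NF-κB list had 0.15. Camera gave the NF-κB list an adjusted p of 0.929 with an estimated correlation. The fry p values given here are not adjusted over the 30 lists. With all 8 libraries the list had a fry adjusted p of 0.125.

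Wild-type replicates 1 and 2 stood apart from the other 6 libraries in composition. Without Rn45s and Lars2, rows that match ribosomal RNA, the gap on the first principal component was 0.999 of its size, but leaving out 2 of 11541 genes could hardly move it, so an effect of ribosomal RNA reads stays open. GC content bias is a candidate explanation, since across genes the log2 ratio of these libraries to wild-type replicates 3 and 4 followed GC content with rho = -0.72, but the gap after the GC correction was 0.68 of its size, so a part remains. For gene length rho was 0.2, between the bounds set for and against it, so length cannot be told apart. No biological explanation was tested, as all 4 libraries carry 1 genotype label and the labels give no batch.

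For the count of called genes, the genotype split gave 0, so all 35 splits gave at least as many by construction and the count of splits says nothing on chance. The highest other count was 5914, for KO replicates 1, 3 and 4 with wild-type replicate 4 against the rest, and 6 other splits had more genes at an unadjusted p under 0.05 than the 752 of the genotype split. These counts point to a structure of the libraries that crosses genotype, along the first principal component, where those 4 libraries had the lowest scores, -24.6 to -15.

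Some genes departed by over 3-fold in a single library. Erdr1, at the pseudoautosomal boundary of the sex chromosomes, was at 1.57 CPM in wild-type replicate 3 and 10.2 to 24.3 CPM in the others. The actin-bundling gene Fscn1 was at 0.261 CPM in wild-type replicate 1 and 1.47 to 5.13 CPM in the others, the basement membrane collagen gene Col4a1 at 0.993 and 3.57 to 12 CPM, and Xlr was at 0.143 CPM in KO replicate 3 and 0.598 to 6.35 CPM in the others.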
